A study of Homo sapiens with 12 samples.

How the data were processed

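Poly(A)-site sequencing reads the 3′ ends of polyadenylated transcripts, so that each read marks where a transcript was cleaved and polyadenylated. It was applied to 12 libraries, 4 of each of 3 kinds of prostate epithelial cell: PrEC, normal primary prostate epithelial cells from a commercial source, and the established prostate cancer lines LNCaP and DU145. Per the labels' protocols, LNCaP and DU145 were grown in RPMI with serum and PrEC in its own epithelial medium, so medium and cell type differ together in both comparisons with PrEC. The series' design text calls the 4 libraries of a line biological replicates, and replicate numbers come from the sample titles. Per the labels' protocols, RNA came from 4 plates of each cell type. Whether each library had its own plate, and whether plates were grown apart in time, is not given in the sources used here, so n = 4 stands for 4 libraries of 1 line or source and p-values measure the spread between these libraries, which may be technical.

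Per the labels' protocols, poly(A)+ RNA was fragmented with alkali, short fragments were selected, and cDNA was made with anchored oligo(dT) primers that carried a sample barcode and degenerate bases. Whether the degenerate bases were used to collapse duplicate reads is not given in the sources used here. Per the submitters' processing notes, reads were aligned with Bowtie2 version 2.2.5 to hg19. How neighbouring cleavage positions were merged into regions, and whether priming at genomic A-rich stretches was filtered, is not given in the sources used here. The deposited values are counts: whole numbers of reads per poly(A) region, not normalized, for 34611 regions with chromosome, strand, start and end, and they were used as deposited. The 12 count columns match the 12 sample titles and 0 further sample columns were present. Coordinates are hg19, counted from 1, with both ends included.

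The regions carry no gene names, and the reference tables at hand describe another genome build, so no region was assigned to a gene, exon, intron or 3′ UTR. The gene of the planned design was therefore replaced by a cluster, defined as regions of 1 strand joined across gaps of up to 2000 bp. This gap was chosen after the counts had been examined, because larger gaps joined what looked like separate transcription units, and gaps of 1000, 5000 and 10000 bp were run as alternatives. A cluster can hold part of a gene or parts of neighbouring genes. For the same reason the 17 gene lists fixed beforehand, the intronic share and the restriction to 3′ UTRs were not run.

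Abundance was tested per region and per cluster with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after filterByExpr by line and TMM scaling, with all 12 libraries in 1 fit and Benjamini-Hochberg adjustment at 0.05. For region usage, regions with at least 5% of a cluster's counts in at least 1 line were retained, in clusters with at least 2 such regions and a mean of at least 10 counts per library in both lines compared. Usage was tested with edgeR's diffSpliceDGE and the Simes p per cluster. The switch test took the 2 retained regions with the largest mean share, ordered them along the strand as proximal and distal, and tested the change of their log ratio with diffSpliceDGE. The distal share is the distal region's percent of the counts of the 2. The mean distal share per library over clusters with at least 10 counts on average in all 3 lines was compared with an exact two-sided permutation test of 4 against 4 libraries, for which the smallest possible p is 0.0286. These tests, their filters and the alternatives not named below as added were fixed before the data were examined, apart from the cluster in place of the gene. DESeq2 1.42.0 and limma 3.58.1 (voom with diffSplice) served as alternatives, along with other size factors, filters and region choices and leaving out each library.

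The naming rule fixed beforehand left out features without a gene symbol and so names nothing here. Pairs and clusters were instead chosen, after their values were seen, by the same ranking: among calls with non-overlapping libraries, the largest changes in distal share (at least 20 counts per library on average over both regions in each line) and in log2 fold change (at least 50 CPM, counts scaled to library size, in the higher line). Named are 4 pairs per direction for each comparison with PrEC, 2 for the comparison of the cancer lines, and 2 clusters per direction throughout, fewer than that rule would have taken. Chromosomes X and Y were left out of everything named. Standard errors of log2 fold changes were derived from the quasi-likelihood F value.

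Replicates 1 and 2 differed from replicates 3 and 4 in every line, a split that the labels do not mention. Whether the replicate numbers pair the libraries was checked through the correlation of deviations from the line means over 26840 regions. Libraries with the same number in different lines correlated with r from 0.598 to 0.724, which by the rule set beforehand treats the numbers as pairing the libraries. Replicates 1 and 2, and replicates 3 and 4, are called batches here from the data alone. Libraries of the same batch with another number correlated as highly, from 0.591 to 0.727, those of opposite batches from -0.726 to -0.598, and 3 of 12 libraries correlated best with their own number in both other lines. The shared component is thus that of the batches. Fits with the replicate number as a block were planned, and fits with the batch as a term and within each batch, simulations in which the lines share the batches and values of named clusters per batch were added after the data were seen. Fits within a batch set 2 libraries against 2 and leave out the spread between batches. Their abundance filter was applied anew, so the number of features tested can differ.

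Total counts ranged from 2176126 to 4133812 per library. Intervals and floors cover counting error only, since reads are not independent molecules. For a line without a count in any library, the floor was 3 counts over the 4 libraries, and 95% exact Poisson intervals are given for ratios against few counts. Replicates of a line differed by more than sampling noise in every pair, with a chi-square per region from 1.19 to 2.51 within batches and from 8.99 to 18.9 across batches, and no library was counted as deposited more than once. LNCaP replicates 3 and 4 were the closest pair, at 1.19. This sets libraries against counting noise alone and does not tell separate cultures from repeat preparations of 1 culture.

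The tests were tried on simulated counts with 200 changed features, drawn for the LNCaP and PrEC comparison from real means pooled over all libraries, library sizes and dispersions. At a 4-fold change the cluster abundance test on 17019 clusters recovered 63.5% of the changed clusters, with 8 false calls among 135. The region test on 24841 regions recovered 59.5%, with 4 false calls among 123. Among 4579 clusters the switch test recovered 68.5% of pairs whose ratio changed 4-fold, with 15 false calls among 152 (9.87%, above the nominal 5%), and the usage test 42.5%, with 2 false calls among 87. At a 2-fold change the recovered shares were 22.5%, 13.5%, 2.5% and 0%. Dispersions included the difference between batches, and few simulated features changed. Both may lower recovery, which was not tested. Simulated libraries were independent and did not share the deviations of a batch as the real ones do. The false calls are therefore not error rates of the real fits.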

Results

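Poly(A) sites were compared between PrEC, LNCaP and DU145, 4 libraries each, to find which sites differ in use between normal and cancerous prostate epithelial cells. Mean total counts were 3612532 ± 426224 in PrEC, 2512938 ± 330296 in LNCaP and 3240917 ± 608007 in DU145 (SD, n = 4 each). The 100 most abundant regions held 23.6% ± 0.813 of the counts in PrEC, 17.5% ± 1.15 in LNCaP and 18.2% ± 0.768 in DU145. The 34611 regions had a median width of 26 bp and formed 22672 same-strand clusters, of which 16433 held 1 region, 3508 held 2 and 2731 held 3 or more. In 5581 clusters at least 2 regions were retained for the analysis of site choice, and the 2 most used lay a median of 542 bp apart.

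Libraries grouped by line first. The first 2 principal components of log2 CPM, with 47.1% and 26.6% of the variance, separated the lines, and PC3, with 19.4%, separated replicates 1 and 2 from replicates 3 and 4, the batches seen in the data, in every line. Log CPM correlated with r from 0.971 to 0.983 across regions between libraries of the same line and batch, and from 0.863 to 0.895 between batches of a line. Correlations across regions describe the libraries and do not treat regions as replicates. Between batches, 10282 of 26840 regions differed in abundance (edgeR, batch as a term).

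**Figure D1:**
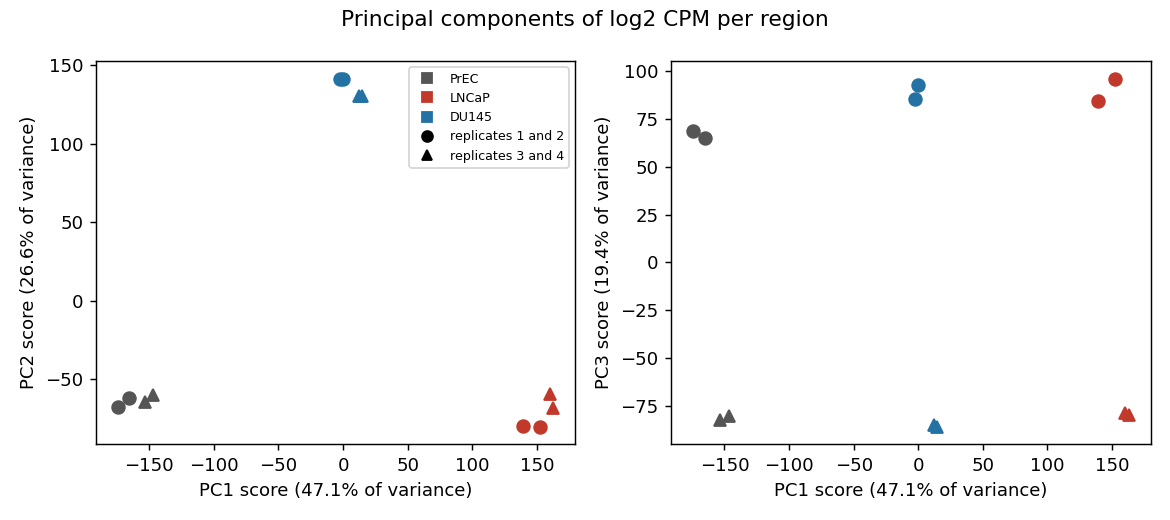
Principal component scores of log2 CPM per region for the 12 libraries, PC1 against PC2 on the left and PC1 against PC3 on the right, with colours for lines and marker shapes for batches. PC1 (47.1%) and PC2 (26.6%) part the lines, and PC3 (19.4%) parts the batches.

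LNCaP used proximal sites more than PrEC. Of 4579 clusters tested, 848 changed the ratio of their 2 main regions, 612 toward the proximal and 236 toward the distal region, so that 72.2% of the calls were toward proximal (diffSpliceDGE, adjusted p under 0.05). With replicates 1 and 2 alone 909 clusters were called, 71.4% of them toward proximal, and with replicates 3 and 4 alone 827, 71.8% toward proximal. A change of at least 10 percentage points was present in 575 of the calls, 409 toward proximal and 166 toward distal. The number of calls rested on the definition of a cluster: joining across gaps of up to 1000 bp gave 552 and up to 10000 bp gave 1511, with 70.1% and 67.0% toward proximal.

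Over the 4474 clusters measured in all 3 lines, the mean distal share was 55.98% ± 0.161 in PrEC, 53.90% ± 0.261 in LNCaP and 55.84% ± 0.319 in DU145 (SD, n = 4 each). LNCaP lay -2.08 percentage points from PrEC (exact permutation p = 0.0286, the smallest possible; 0.0429 after Benjamini-Hochberg adjustment over 3 comparisons), and all 4 LNCaP libraries were below all 4 PrEC libraries. Within replicates 1 and 2 the difference was -2.43 points and within replicates 3 and 4 -1.73 points. Paired by replicate number, an exact sign-flip test of the block gave p = 0.125, the smallest that 4 pairs allow.

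**Figure D2:**
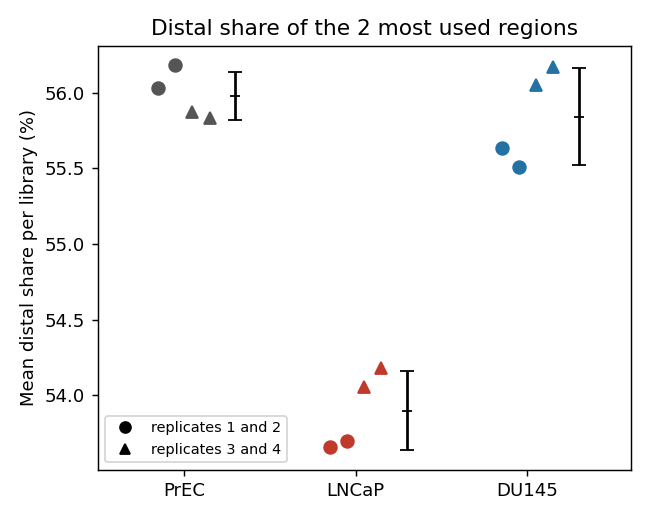
Mean distal share per library (percent, y axis, which does not start at 0) over 4474 clusters, for each line, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean ± SD of 4 libraries. The LNCaP libraries, with a mean of 53.90%, lie below those of PrEC (55.98%) and DU145 (55.84%).

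The shift in LNCaP was present at each spacing of the regions. For pairs under 100 bp apart, 83 calls were toward proximal and 8 toward distal, and the mean distal share over 552 clusters was -3.37 points from PrEC. It was -1.39 points for 1572 clusters with pairs at least 100 and under 500 bp apart, -2.02 for 2114 clusters at 500 to under 2000 bp, and -4.27 for 236 clusters at 2000 bp or more. Each of these had an exact permutation p of 0.0286 (adjusted over 12 comparisons 0.0429), a division by spacing made after the data were seen. The permutation does not pair the libraries by replicate number, and a sign-flip test of 4 pairs allows no p under 0.125. The sign held within both batches at each spacing, with the values of replicates 1 and 2 and of replicates 3 and 4 at -3.61 and -3.13, -1.37 and -1.40, -2.63 and -1.41, and -4.94 and -3.59 in order of spacing.

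**Figure D3:**
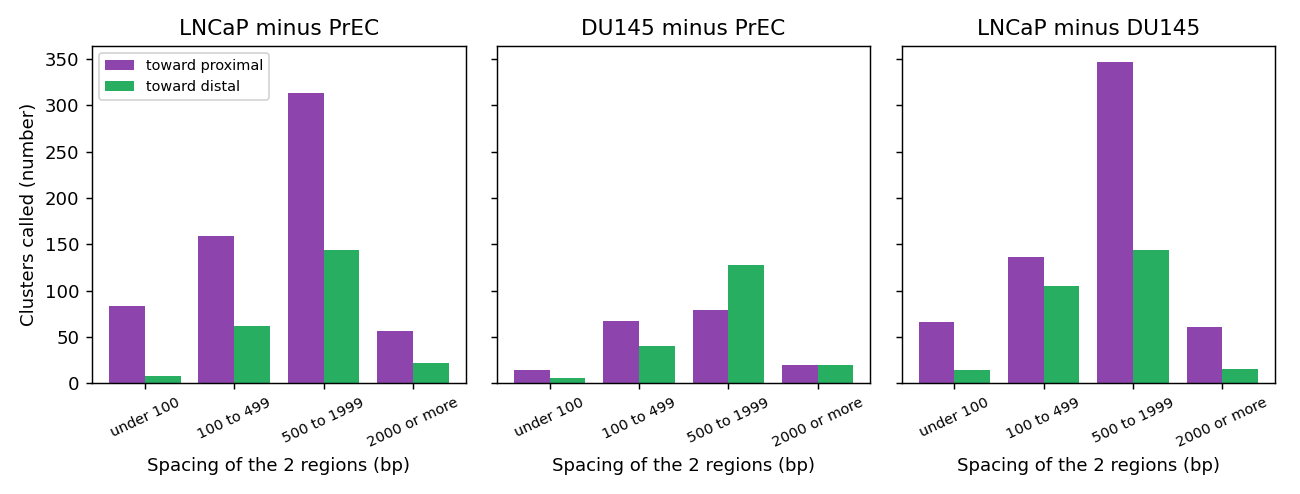
Number of clusters called by the switch test (y axis) by the spacing of the 2 regions in bp (x axis), for each comparison, toward the proximal (purple) or the distal region (green). In LNCaP minus PrEC, 83 calls under 100 bp were toward proximal and 8 toward distal, and at 500 to under 2000 bp 314 and 144.

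Among the pairs with the largest falls in distal share in LNCaP was 1 on chromosome 6, plus strand, with the proximal region at 28243588 to 28243591 and the distal at 28245973 to 28245996. Its distal share was 73.7% ± 12.4 in PrEC and 17.7% ± 13.7 in LNCaP (SD, n = 4 each, adjusted p = 0.000118), on 23 and 24.8 counts per library, and the proximal region was only 4 bp wide. On the minus strand of chromosome 6, a pair at 18130537 to 18130560 and 18128538 to 18128557 went from 73.1% ± 10.1 to 25.3% ± 6.23 (adjusted p = 2.19e-05). A pair on chromosome 14, minus strand, at 60616095 to 60616127 and 60615622 to 60615640 went from 68.7% ± 8.39 to 22.0% ± 13.5 (adjusted p = 0.00199). On chromosome 3, plus strand, a pair at 73116322 to 73116355 and 73118338 to 73118362 had a distal share of 64.2% ± 5.49 in PrEC, 19.5% ± 3.51 in LNCaP (adjusted p = 1.37e-07) and 38.3% ± 0.759 in DU145.

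Toward the distal region, a pair on chromosome 15, plus strand, at 90820817 to 90820837 and 90821098 to 90821124 rose from 12.03% ± 5.76 in PrEC to 87.2% ± 5.62 in LNCaP (adjusted p = 1.37e-07). On chromosome 6, minus strand, a pair at 42931732 to 42931753 and 42931599 to 42931625 rose from 18.9% ± 7.41 to 78.0% ± 4.48 (adjusted p = 1.87e-06). A pair on chromosome 19, minus strand, at 47990889 to 47990911 and 47990474 to 47990478 rose from 21.7% ± 7.36 to 79.3% ± 18.1 (adjusted p = 0.00504), with a distal region only 5 bp wide. That rise was 78.8 points within replicates 1 and 2 and 36.3 within replicates 3 and 4. The largest rise, from 8.68% ± 9.74 to 89.9% ± 2.68 (adjusted p = 2.53e-07), was at 566043 to 566067 and 567579 to 567648 on chromosome 1, plus strand. That stretch of hg19 is a near-identical copy of mitochondrial DNA, so its reads are not uniquely placed and the value is uncertain.

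**Figure D4:**
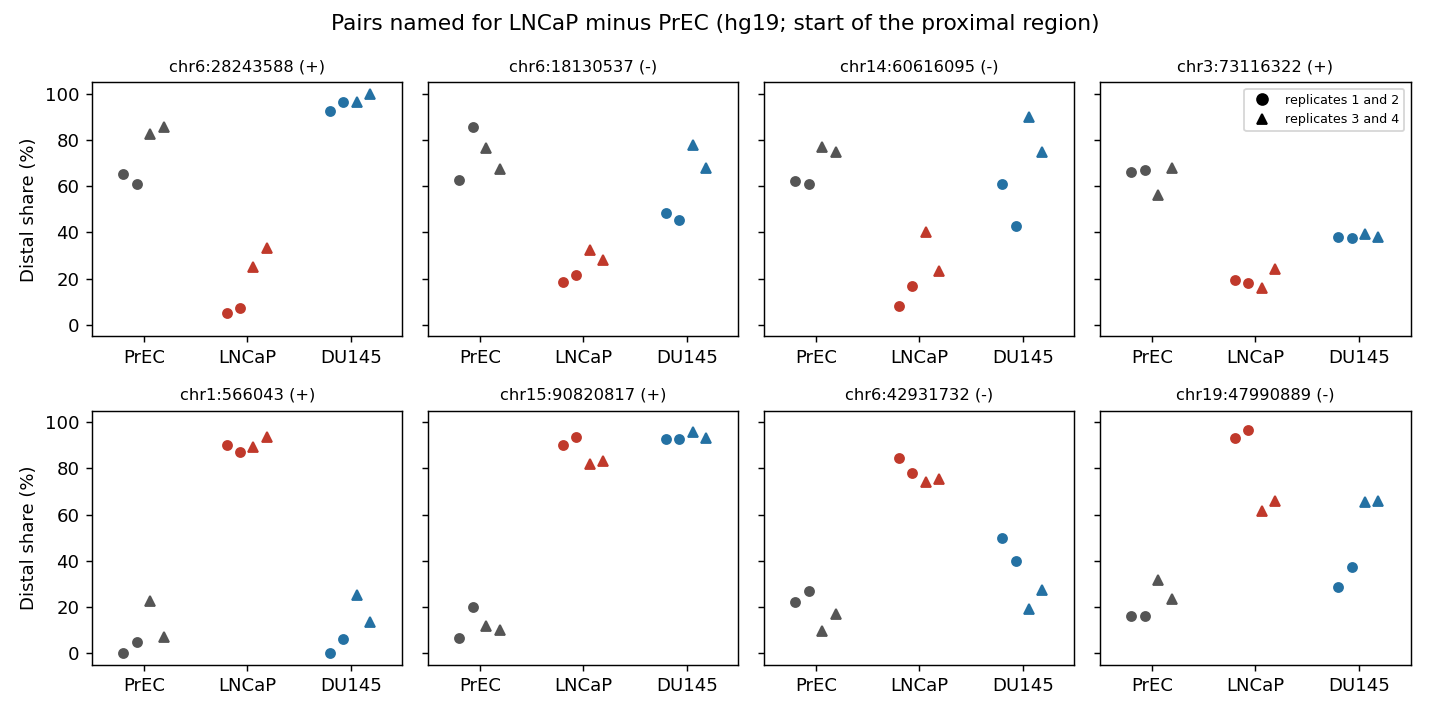
Distal share (percent, y axis) of the 8 pairs named for LNCaP minus PrEC in each library of the 3 lines, titled by chromosome, start of the proximal region and strand; circles are replicates 1 and 2, triangles replicates 3 and 4. In each panel the 4 LNCaP libraries do not overlap the 4 PrEC libraries, as the choice of pairs required.

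Any change in the use of regions, tested over all retained regions of a cluster, was called in 306 of 4579 clusters for LNCaP against PrEC, and in 936 with the replicate block. Leaving out LNCaP replicate 2 gave 201. Within replicates 1 and 2 there were 697 calls and within replicates 3 and 4 582.

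Abundance differed widely between LNCaP and PrEC. Of 18219 clusters tested, 11223 differed (5561 higher and 5662 lower in LNCaP), with a median absolute log2 fold change of 1.72, and 2148 were at least 4-fold higher and 2730 at least 4-fold lower. Per region, 16021 of 26840 differed, 7733 higher and 8288 lower. Within replicates 1 and 2 there were 14486 cluster calls and 20186 region calls, and within replicates 3 and 4 12206 and 17163, each after a filter of its own.

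The cluster on chromosome 17, minus strand, at 4532997 to 4534272 had 66.4 ± 3.04 CPM in LNCaP and 1 count over the 4 PrEC libraries, a ratio of 789 (95% Poisson interval 142 to 31162, edgeR adjusted p = 6.76e-09). That count lay in PrEC replicate 1, and without this library the fitted log2 fold change went from 9.06 to 10.69. The ratio was 403 (72.3 to 15903) in replicates 1 and 2, and in replicates 3 and 4, without a PrEC count, LNCaP was at least 129-fold higher at a floor of 3 counts over the 2 libraries. At 50526129 to 50526351 on chromosome 7, minus strand, LNCaP had 276 ± 19.0 CPM and PrEC 0.504 ± 0.661, a ratio of 547 (251 to 1490). The fitted log2 fold change was 8.98 (SE 0.63) and 10.01 without PrEC replicate 1. In replicates 1 and 2 PrEC had 6 counts, a ratio of 294, and in replicates 3 and 4 no count, at least 507-fold at the same floor. Higher in PrEC were the clusters at 82877248 to 82878126 on chromosome 5, plus strand, with 95.0 ± 50.8 CPM, and at 43805180 to 43805188 on chromosome 20, plus strand, with 64.1 ± 7.92 CPM. Each had 1 count over the 4 LNCaP libraries, in replicate 1, so that PrEC was higher by a ratio of 1050 (189 to 41487) and 708 (127 to 27981). These ratios were 287 (51.5 to 11331) and 386 (69.2 to 15228) within replicates 1 and 2, and within replicates 3 and 4, without an LNCaP count, at least 252-fold and 108-fold. Without LNCaP replicate 1 the fitted log2 fold changes went from -9.50 to -11.24 and from -8.94 to -10.68. In all, 95 regions with a mean of at least 20 counts in LNCaP had no count in any PrEC library, and 226 such regions of PrEC had none in LNCaP. These limits were set on raw counts, and PrEC libraries were deeper on average than LNCaP libraries. The numbers 95 and 226 are thus not directly comparable.

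DU145 changed site choice without a common direction over all spacings. Of 4818 clusters tested against PrEC, 374 changed the ratio of their 2 main regions, 180 toward proximal and 194 toward distal, and with the replicate block 639, 321 toward proximal and 318 toward distal. Of the 374 calls 365 were also called with the block. Within replicates 1 and 2 there were 489 calls, 54.2% toward proximal, and within replicates 3 and 4 510, 45.3% toward proximal. A change of at least 10 points was present in 239 calls. With gaps of up to 1000, 5000 and 10000 bp the calls numbered 222, 650 and 964.

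The mean distal share of DU145 was -0.137 points from PrEC, a difference smaller than the spread between libraries (exact permutation p = 0.429), and it was -0.535 within replicates 1 and 2 and 0.260 within replicates 3 and 4. With gaps of up to 1000 bp it was -0.343 (exact permutation p = 0.0286, before adjustment). For pairs under 100 bp apart it was -0.964 points (exact permutation p = 0.0286, adjusted 0.0429), with -1.15 and -0.773 in the batches. At 100 to under 500 bp it was -0.693, at 500 to under 2000 bp 0.405 and at 2000 bp or more 0.636, none past the test (exact permutation p = 0.0857, 0.171 and 0.314; adjusted 0.103, 0.187 and 0.314). At both of the longest spacings the sign differed between the batches (-0.111 and 0.922, and -0.524 and 1.80). The permutation tests of these DU145 differences do not pair the libraries by replicate number, and a sign-flip test of 4 pairs allows no p under 0.125. Calls toward proximal and distal numbered 14 and 6, 67 and 40, 79 and 128, and 20 and 20 in order of spacing.

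The same pair on chromosome 15 that rose in LNCaP, at 90820817, had a distal share of 93.6% ± 1.35 in DU145 against 12.03% ± 5.76 in PrEC (SD, n = 4 each, adjusted p = 2.08e-08). On chromosome 5, minus strand, a pair at 114950642 to 114950674 and 114949192 to 114949218 rose from 30.5% ± 6.68 to 75.5% ± 14.3 (adjusted p = 0.00153), and on chromosome 14, minus strand, a pair at 23369942 to 23370002 and 23369850 to 23369877 rose from 8.82% ± 4.64 to 52.7% ± 13.2 (adjusted p = 2.17e-05). The rise at 114950642 was 28.9 points within replicates 1 and 2 and 61.1 within replicates 3 and 4. The largest rise, from 6.72% ± 4.65 to 88.6% ± 2.95 (adjusted p = 3.22e-10), was on chromosome 17, plus strand, at 22020727 to 22020769 and 22023766 to 22023864. This stretch too holds a copy of mitochondrial sequence, and the value is uncertain.

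Toward the proximal region, a pair on chromosome 22, plus strand, at 31673328 to 31673346 and 31673612 to 31673632 fell from 72.4% ± 8.46 in PrEC to 29.1% ± 21.9 in DU145 (adjusted p = 0.00859). That mean joins unlike batches, with a change of -55.3 points within replicates 1 and 2 and -31.3 within replicates 3 and 4. Without DU145 replicate 1 it fell by 37.1 points with an adjusted p of 0.0746, the highest of its 19 alternatives, of which the lowest was 6.54e-09. A pair on chromosome 11, plus strand, at 68855862 to 68855910 and 68855947 to 68855997 fell from 79.6% ± 2.56 to 39.7% ± 13.5 (adjusted p = 8.45e-05; -30.8 and -49.0 points within the batches), and on chromosome 3, minus strand, a pair at 196745967 to 196745980 and 196745810 to 196745832 fell from 95.9% ± 1.15 to 63.0% ± 6.24 (adjusted p = 3.34e-06). A pair on chromosome 13, plus strand, at 73329579 to 73329595 and 73330328 to 73330341 fell from 51.6% ± 20.5 to 13.4% ± 13.5 (adjusted p = 0.0323). That call was lost without PrEC replicate 1 (adjusted p = 0.112), PrEC replicate 2 (0.0895), DU145 replicate 3 (0.0604) or DU145 replicate 4 (0.120), and with only the 8 libraries of the comparison (0.0580), in a range from 0.000174 to 0.120 over 21 alternatives.

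Use of regions changed in 92 of 4818 clusters for DU145 against PrEC, and in 462 with the replicate block, with 306 calls within replicates 1 and 2 and 335 within replicates 3 and 4. In abundance 9924 of 18219 clusters differed, 4753 higher and 5171 lower in DU145, with a median absolute log2 fold change of 1.49, and within the batches 13444 and 11379. Of 26840 regions 14122 differed, 6510 higher and 7612 lower, and within the batches 18590 and 15968. The abundance fits within the batches had filters of their own.

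The cluster on chromosome 17, minus strand, at 39738524 to 39740529 had 199 ± 199 CPM in PrEC and no count in any DU145 library, so that PrEC was at least 952-fold higher over the pooled libraries (edgeR adjusted p = 0.000412). That mean joins unlike batches: PrEC had 27.2 CPM in replicates 1 and 2, at least 67.4-fold higher at a floor of 3 counts over the 2 DU145 libraries, and 371 CPM in replicates 3 and 4, at least 855-fold higher. The cluster on chromosome 13, minus strand, at 38136716 to 38137271 had 131 ± 69.4 CPM in PrEC and no count in DU145, at least 625-fold higher in PrEC (edgeR adjusted p = 1.35e-05), with at least 471-fold in replicates 1 and 2 and 165-fold in replicates 3 and 4. Higher in DU145 were the clusters on chromosome 14, minus strand, at 37180451 to 37180505, with 74.7 ± 8.60 CPM against 2 counts over PrEC, a ratio of 443 (95% Poisson interval 123 to 3662), and on chromosome 12, minus strand, at 16701295 to 16703947, with 103 ± 17.5 CPM against 3 counts, a ratio of 409 (140 to 1986). In replicates 1 and 2 these were at least 146-fold and a ratio of 182 (62.2 to 881), and in replicates 3 and 4 a ratio of 224 (62.1 to 1851) and at least 227-fold. The 2 counts of the former lay in PrEC replicate 3, without which its fitted log2 fold change went from 8.49 to 10.84, and for the latter the fitted log2 fold change went from 8.46 to 9.35 without PrEC replicate 2. A mean of at least 20 counts in DU145 with no count in PrEC was found for 36 regions, and the opposite for 235. Raw counts were used here too, and PrEC libraries were deeper on average than DU145 libraries.

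The cancer lines differed from each other in site choice about as often as LNCaP differed from PrEC. Of 4654 clusters tested, 888 changed the ratio of their 2 main regions between LNCaP and DU145, 610 toward proximal and 278 toward distal in LNCaP (68.7% toward proximal). Within replicates 1 and 2 there were 923 calls, 66.3% toward proximal, and within replicates 3 and 4 933, 68.7% toward proximal. A change of at least 10 points was present in 602. With gaps of up to 1000 bp there were 561 calls, with gaps of up to 10000 bp 1519, and with the batch as a term 1366.

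The mean distal share of LNCaP was -1.95 points from that of DU145 (exact permutation p = 0.0286, the smallest possible; 0.0429 after Benjamini-Hochberg adjustment), with -1.90 within replicates 1 and 2 and -1.99 within replicates 3 and 4. Paired by replicate number, an exact sign-flip test of the block gave p = 0.125, the smallest possible. By spacing, the difference was -2.40 points for pairs under 100 bp apart, -2.43 at 500 to under 2000 bp and -4.90 at 2000 bp or more (exact permutation p = 0.0286 for each, adjusted 0.0429). At 100 to under 500 bp it was -0.694 (exact permutation p = 0.0857, adjusted 0.103).

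The pair on chromosome 6 at 28243588, named above for its fall in LNCaP against PrEC, had a distal share of 17.7% ± 13.7 in LNCaP and 96.4% ± 3.03 in DU145 (SD, n = 4 each, adjusted p = 2.85e-07). On chromosome 10, plus strand, a pair at 16555443 to 16555456 and 16555728 to 16555762 had 17.0% ± 8.998 in LNCaP and 74.3% ± 11.4 in DU145 (adjusted p = 7.06e-05). Higher in LNCaP was the distal share of a pair on chromosome 19, plus strand, at 21131661 to 21131686 and 21133484 to 21133517, with 99.0% ± 2.08 against 51.8% ± 4.61 (adjusted p = 6.71e-05). On the minus strand of chromosome 19, a pair at 2428155 to 2428191 and 2426538 to 2426609 had 85.2% ± 2.90 in LNCaP and 42.7% ± 5.31 in DU145 (adjusted p = 2.91e-07).

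Use of regions differed between the cancer lines in 337 of 4654 clusters, in 1047 with the replicate block, and in 691 and 701 within the batches. Without LNCaP replicate 1 it differed in 222. In abundance 9934 of 18219 clusters differed, 5094 higher and 4840 lower in LNCaP, with a median absolute log2 fold change of 1.52, and within the batches 12510 and 11369. Of 26840 regions 13813 differed, 7033 higher and 6780 lower, and within the batches 17062 and 15573, again after filters of their own.

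The cluster on chromosome 13, minus strand, at 72780572 to 72780576 had 91.6 ± 57.4 CPM in LNCaP and 0.336 ± 0.495 in DU145, a ratio of 329 (95% Poisson interval 128 to 1208). It is 1 region narrower than 6 bp, and its mean joins unlike batches. LNCaP had 141 CPM in replicates 1 and 2, a ratio of 349 (119 to 1691). In replicates 3 and 4 it had 42.6 CPM, a ratio of 295 (53.0 to 11654) on 1 DU145 count. On chromosome 11, minus strand, the cluster at 111164110 to 111164178 had 68.0 ± 5.96 CPM in LNCaP and 0.426 ± 0.669 in DU145, a ratio of 163 (74.8 to 444). At the latter DU145 had no count in replicates 1 and 2, at least 160.4-fold at a floor of 3 counts over those 2 libraries, and 6 in replicates 3 and 4, a ratio of 82.4. Higher in DU145 were the clusters on chromosome 19, plus strand, at 48833807 to 48833821, with 51.6 ± 45.7 CPM against 0.503 ± 0.541 in LNCaP (90.9 CPM in replicates 1 and 2 and 12.3 in replicates 3 and 4 of DU145, ratios of 102 and, on 1 LNCaP count, 67.0 with an interval of 12.02 to 2645), and on chromosome 20, plus strand, at 43356430 to 43356459, with 59.7 ± 2.80 CPM against 0.870 ± 1.31 (ratios of 347, on 1 LNCaP count with an interval of 62.2 to 13688, and 39.3 within the batches). Leaving out 1 library moved the fitted log2 fold changes of these 4 clusters, in the order given, from 8.15 to 9.48 without DU145 replicate 2, from 7.21 to 8.99 without DU145 replicate 4, from -6.49 to -7.45 without LNCaP replicate 2 and from -6.11 to -7.77 without LNCaP replicate 3. With at least 20 counts on average in 1 of the cancer lines and no count in the other, 40 regions were found in LNCaP and 20 in DU145. These too are raw counts, and DU145 libraries were deeper on average than LNCaP libraries.

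Clusters called in both cancer lines against PrEC mostly changed in the same direction. Of 4474 clusters tested in both comparisons, 73 were called toward proximal in both lines, where independent lists of 607 and 175 would share 23.7, and 65 toward distal in both, where lists of 235 and 186 would share 9.77. Another 24 were called in opposite directions. The comparisons share the PrEC libraries. With these divided, so that each comparison used 2 of them and none was shared, 19.25 clusters on average over 4 divisions were called in the same direction (17 to 21), where independent lists would share 3.06, and 1.25 in opposite directions, where they would share 3.64. With the batch as a term these were 129 (117 to 137) against 37.3 and 25 against 37.6. The divided PrEC libraries still come from 1 source in its own medium, with both batches in each part. A trait of PrEC or its medium thus enters both comparisons. The overlap cannot tell such a trait from a change shared by the cancer lines. Simulations without any effect gave hardly any calls (0.45 for LNCaP and 0.40 for DU145 on average over 20), so their overlap of at most 1 is no measure for lists as long as the real ones. Over 4474 clusters the covariance of the log2 changes was 0.292, against 0.153 in these simulations, which ignore the batches, and 0.0753 where the simulated lines shared the batches. The correlation across clusters, r = 0.431, lay below the 0.496 and 0.502 of the simulations, where only chance values and the shared libraries contribute.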

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

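The thinning of libraries and the comparison of LNCaP with DU145 were fixed beforehand, but their use to weigh an explanation, the other tests that weigh one and the choice of pairs and clusters named came only after the results were seen.

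In 8 of 72 groups of 4 libraries, 1 library lay far from the other 3, where chance sets apart about 1 in 20 groups, or 3.6 of these. In 5 of the 8 the other 3 libraries were all at 0 or all at 100%, where any different value counts as far, so the excess over 3.6 says nothing. The distal share of the chromosome 3 pair at 73116322 was 56.1% in PrEC replicate 3 and 66.0% to 67.9% in the others. That of the chromosome 15 pair at 90820817 was 95.7% in DU145 replicate 3 (others 92.9% to 93.2%), and that of the chromosome 19 pair at 21131661 was 95.8% in LNCaP replicate 3 (others 100%). Near zero counts, the chromosome 17 cluster at 4532997 had 0.348 CPM in PrEC replicate 1, the chromosome 14 cluster at 37180451 had 0.601 CPM in PrEC replicate 3, and the clusters at 82877248 on chromosome 5 and 43805180 on chromosome 20 had 0.406 CPM each in LNCaP replicate 1, with 0 in the other libraries. The chromosome 20 cluster at 43356430 had 2.83 CPM in LNCaP replicate 3 and 0 to 0.337 in the others.

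LNCaP and DU145 differed from PrEC by different amounts at several named features, by a test of LNCaP against DU145 itself (diffSpliceDGE for pairs, edgeR's quasi-likelihood test for clusters, both with Benjamini-Hochberg adjustment). These features were chosen as the largest changes of a cancer line against PrEC. Its libraries enter this test again, so a difference is favoured. Over all features, 888 of 4654 pairs and 9934 of 18219 clusters differed between the cancer lines. Features named against PrEC and not listed here were not called or not tested. The distal share in LNCaP minus DU145 was -78.7 points at 28243588 on chromosome 6, -34.6 at 18130537 on chromosome 6 (adjusted p = 0.000602), -45.2 at 60616095 on chromosome 14 (adjusted p = 0.0104), -18.8 at 73116322 on chromosome 3 and 44.0 at 42931732 on chromosome 6. It was 36.5 points at 68855862 on chromosome 11, -45.7 at 114950642 on chromosome 5 and -42.4 at 23369942 on chromosome 14. At the uncertain pairs in copies of mitochondrial sequence it was 78.7 at 566043 on chromosome 1 and -32.9 at 22020727 on chromosome 17. Some of these pairs fell below the 20 counts per library asked when pairs were named. DU145 had 12.5 on average at 60616095, 16.25 at 42931732 and 15.5 at 566043, and LNCaP 19.25 at 22020727. The fitted log2 fold change, which depends on the prior count, was 6.79 for the cluster at 4532997 on chromosome 17, 6.71 at 50526129 on chromosome 7, -3.45 at 43805180 on chromosome 20, -4.76 at 37180451 on chromosome 14 and -5.47 at 16701295 on chromosome 12. At several of these the lower line had few counts, spread unevenly over its libraries. LNCaP had 1 to 14 counts per library at 37180451 and 1 to 15 at 16701295, the most in replicate 3. At 43805180 it had 1 count, in replicate 1, and DU145 only 4 to 6 counts per library, so both cancer lines were near zero there. At 50526129 DU145 had 0.655 and 0.349 CPM in replicates 1 and 2, and 5.34 and 4.22 in replicates 3 and 4.

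The mean distal share also differed between the cancer lines, by -1.95 points in LNCaP minus DU145. As LNCaP and DU145 shared a medium, this argues against the medium of PrEC as the whole cause of the lower share in LNCaP. Lower depth of the LNCaP libraries is argued against by the difference from PrEC of -2.06 points after thinning every library to the smallest total, and the batches by the smaller of the within-batch differences, -1.73 points. A difference between the cell lines themselves remains a candidate explanation and was not tested separately, as each kind of cell was a single line or source.

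Regions narrower than 6 bp held 2.09% ± 0.286 of the counts in replicates 1 and 2 (SD, n = 6) and 0.227% ± 0.0337 in replicates 3 and 4. In each line at least 97.4% of them were higher in replicates 1 and 2, as preparation or sequencing that differed between the batches could give. Against deeper sequencing, the deepest library of replicates 3 and 4 had 0.156 of the share in the shallowest of replicates 1 and 2. Against the cell lines, their means within replicates 1 and 2 spanned 0.195 of the difference between the batches.

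Regions abundant in PrEC had a raised floor in LNCaP replicate 1: the 5th percentile of the ratio to PrEC was 2.48% there, 1.21% in replicate 2, and 0.210% and 0.221% in replicates 3 and 4. The quotient of 11.5 sets replicate 1 against replicates 3 and 4, the other batch. In DU145 this percentile was 0.724% and 0.735% in replicates 1 and 2, and 0.468% and 0.213% in replicates 3 and 4. Reads from PrEC material in LNCaP replicate 1 could give its raised floor, as could other sources not tested. A floor raised in the whole batch is not told apart from such reads. An earlier test, the share of regions within a factor of 1.5 of a common ratio, depended on the limit used to choose regions (90.4% at 2% to 53.6% at 20%), which is why the test without a limit was added, and it leaves the question open. Expression by LNCaP cells stays open as well, as the ratio in replicates 3 and 4 reached 0.612 of that in replicate 1 at the widest limit and 0.167 at the narrowest. For DU145 regions in LNCaP replicate 3 the same quotient was 1.89, too small to decide, although the lowest ratio to DU145 was 3.08% there, 1.42% in replicate 4 and 0.406% and 0.297% in replicates 1 and 2, and DU145 reads in that library stay open.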

How the results depend on the processing

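The fits with a batch term, within a batch, with other gaps and without narrow or closely spaced regions were chosen after the data were seen. So were, for the clusters shared by the cancer lines, the fits with limma's diffSplice and without 1 library and the division of PrEC with the batch term, and the others were planned. Calls of abundance per region and per cluster stayed within 1.5 times in every alternative run, with clusters from 8452 to 14486 for LNCaP minus PrEC, 6994 to 13444 for DU145 minus PrEC and 6950 to 12569 for LNCaP minus DU145. Over the values that answer a comparison, 286 alternatives stayed, 47 moved, 1 became stronger and 2 weaker. For numbers of calls, including those shared by the cancer lines, staying meant only a number within 1.5 times the main one. It does not cover their direction or which features were called. A mean distal share stayed if its p kept its side of the threshold. Without a p, it stayed if it lay within the spread between libraries. Over named pairs and clusters 593 alternatives kept the call, 6 lost the call and 0 reversed. These features were chosen as the largest changes among calls in the same data, so the tally says little about other calls.

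Counts follow in the order LNCaP minus PrEC, DU145 minus PrEC and LNCaP minus DU145. Use of regions, called in 306, 92 and 337 clusters, was called in 936, 462 and 1047 with the replicate block, 1010, 519 and 1133 with the batch term, and 804, 366 and 922 with limma's diffSplice. Gaps of up to 1000 bp gave 143, 49 and 149, of up to 5000 bp 567, 277 and 631, and of up to 10000 bp 850, 543 and 850. Replicates 1 and 2 alone gave 697, 306 and 691, and replicates 3 and 4 alone 582, 335 and 701. Leaving out 1 library gave 201 to 234, 63 to 79 and 222 to 264, of which 201 without LNCaP replicate 2 and 222 without LNCaP replicate 1 moved by over 1.5 times.

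Switch calls for DU145 minus PrEC, 374, became 639 with the block, 711 with the batch term, 239 at 10 points or more and 650 with gaps of up to 5000 bp, and those of LNCaP minus DU145 became 1366 with the batch term. Gaps of up to 1000 bp gave 552, 222 and 561 and of up to 10000 bp 1511, 964 and 1519. Without 1 library they ranged from 697 to 740, 268 to 298 and 733 to 778. The 138 clusters shared by the cancer lines became 248 with the block, 275 with the batch term, 74, 251 and 431 with gaps of up to 1000, 5000 and 10000 bp, and 19.25 with PrEC divided between the comparisons, which leaves 2 PrEC libraries in each. Wider gaps join more regions and so test other clusters, and for the other changes the cause was not tested.

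The mean distal share differed by -2.08 points for LNCaP minus PrEC and -1.95 for LNCaP minus DU145, and under the replicate block the exact sign-flip p was 0.125 for both, the smallest that 4 pairs allow. DU145 minus PrEC was -0.343 with gaps of up to 1000 bp (exact permutation p = 0.0286). Within replicates 1 and 2 it was -0.535, and -2.43 for LNCaP minus PrEC, and within replicates 3 and 4 0.260 and -1.73. Apart from these means, the block ended no call among the values above.

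The gene list tests, the intronic share and the restriction to 3′ UTRs were not run, as no annotation of the build was used here, nor were the pseudocount alternatives, as the values are counts. The calls lost were those of the pairs at 73329579 on chromosome 13, in 5 alternatives, and at 31673328 on chromosome 22, in 1, and the cause was not tested. With the replicate block their adjusted p in diffSpliceDGE was 0.000474 and 1.3e-06, in ranges from 0.000174 to 0.120 and 6.54e-09 to 0.0746 over the alternatives.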

Other observations

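Apart from the other splits of the libraries, the tests in this part were chosen only after the results were seen.

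Clusters of the same stretch of chromosome tended to change together in DU145 against PrEC. In windows of 10 Mb with at least 15 clusters (279 windows, 17553 clusters), the SD of window medians of the log2 fold change was 0.45 for DU145 minus PrEC, where permuted positions gave a mean of 0.24, and 0.48 against 0.29 for LNCaP minus PrEC. Clusters can be pieces of 1 gene that change together anyway, so the permutation was repeated with only clusters of a strand at least 200 kb or at least 1000 kb apart, in windows with at least 5 of them. For DU145 minus PrEC the SD was then 0.46 against a permuted mean of 0.35 (permutation p = 0.002) and 0.57 against 0.50 (permutation p = 0.00899). For LNCaP minus DU145 it was 0.43 against 0.31 (permutation p = 0.003) and 0.53 against 0.45 (permutation p = 0.000999, the smallest possible). For LNCaP minus PrEC it was 0.53 against 0.45 (permutation p = 0.0130) and 0.67 against 0.67 (permutation p = 0.412), and whether windows change together there stays open. These p-values were not adjusted over the 6 tests. Over all clusters the lowest median in DU145 minus PrEC was -1.94 at 150000001 to 160000000 on chromosome 4, with 41 of 50 lower, and the highest 1.68 at 30000001 to 40000000 on chromosome 14, with 69 of 76 higher.

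Gene dosage or regulation that acts on a whole stretch, in DU145 or in PrEC, may underlie this, and would move both strands, whereas pieces of 1 gene lie on 1 strand. Window medians of the strands correlated in DU145 minus PrEC over 272 windows (r = 0.460, rho = 0.453, permutation p = 1e-05, the smallest possible), which is consistent with it. In LNCaP minus PrEC r was 0.118 (rho = 0.153, permutation p = 0.0545), which leaves it open. Windows are not independent replicates, and copy number was not measured here.

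Against PrEC, clusters that shifted to the proximal region in LNCaP were not higher in abundance than those that shifted to the distal region. In LNCaP minus PrEC the median log2 fold change was -0.12 for the 612 clusters that shifted toward proximal and 0.12 for the 236 that shifted toward distal, a difference of -0.24 (permutation p = 0.0049). In DU145 minus PrEC the difference was -0.18 (permutation p = 0.188) and in LNCaP minus DU145 -0.12 (permutation p = 0.120), which decide nothing. These permutations shuffled the direction among called clusters. They take clusters as independent units and do not measure the spread between libraries. Abundance and direction also come from the same counts.

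Whether chance could give as many calls was tested by refitting the 8 libraries of a comparison under all 35 splits into 4 and 4. For region abundance the real split gave 14258 calls for LNCaP minus PrEC, 13388 for DU145 minus PrEC and 12522 for LNCaP minus DU145, and the highest other 1162, 1899 and 2302. For cluster abundance these were 10310, 9554 and 9375 against 922, 1487 and 1828. For LNCaP minus PrEC and LNCaP minus DU145, use of regions gave 288 and 313 against 80 and 122, and switches 762 and 876 against 259 and 359. In these 10 results only 1 of the 35 splits, the real one, gave as many calls, the smallest share possible. The other splits mix the lines in each group, so that a line difference adds to the spread within groups and lowers their calls. The count thus shows that libraries group by line, and it cannot exclude chance as a source of individual calls. The 35 splits ignore the batches, and of the 8 that part every replicate pair the real one alone gave calls, but 8 splits are too few for a share under 0.05.

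For DU145 minus PrEC the real split was not even the highest, since 2 of 35 splits gave as many calls: use of regions gave 93 in the real split against 159, and switches 326 against 354. Chance could not be excluded by that count here either. The split as large was the one that puts replicates 1 and 2 against replicates 3 and 4, and it was also the highest other split in the 10 results above. All remaining splits gave 0 calls in each of the 12 results. Among the 8 splits that part every replicate pair, DU145 minus PrEC thus looked like the other comparisons, with the same limit. With the replicate block DU145 minus PrEC had 462 and 639 calls, and within the batches 306 and 335 for use of regions and 489 and 510 for switches.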
